A study of Danio rerio with 37 samples.

How the data were processed

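Messenger RNA was measured in liver and intestine of zebrafish (wild type AB Tübingen) that had been fed brine shrimp nauplii exposed to silver nanoparticles of 5 nm coated with PVP/PEI, or unexposed nauplii, for 3 or 21 days. The arrayed dose was 0.1 mg/L silver in the nauplii's water, called C1 in the labels, and a lower dose of 0.001 mg/L was part of the protocol without arrays. Per the labels all 37 samples came from male fish. Per the series text, each group held 20 fish, and each of 5 replicates pooled 4 livers or 4 intestines. RNA had an integrity number above 8.1, and 100 ng were labelled with Cy3 (labelling protocol version 6.5) and hybridised to an Agilent zebrafish array with 1 colour.

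Per the file headers, the scanner files hold fluorescence intensity per spot, which Agilent Feature Extraction 10.7.3.1 had background subtracted and detrended within each array, with no normalization between arrays. Probe positions in those files refer to the genome build Zv9. The deposited value table holds log2 values for 38144 probes in 37 columns. Over 22572 bright probes its columns differed from the quantile-normalized log2 processed signal by a median of 0.000717, after a constant per probe, against 0.0561 for signals shifted by 1 constant per array. The largest absolute mean of a probe over its 37 columns was 5.41e-06, so that the table gives each probe relative to its own mean. The comparisons used the scanner files, and the value table served as an alternative source.

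Each array carried 45220 spots, of which 43803 were not controls, for 43603 probes. Control spots were left out and spots of the same probe were averaged. The log2 processed signal of each array was shifted by its 75th percentile, so that all levels are log2 signal relative to the 75th percentile of the same array. Probes entered a tissue's tests when well above background on at least 4 arrays of that tissue. Between 69.6% and 82.4% of an array's spots were well above background (median 76.6%), the 75th percentile of the signal lay between 143 and 514 (median 316), 2 to 149 spots per array (median 10) were marked as outliers by the extraction software, 0 were saturated, and the spike-in slope was 0.935 to 1.05. The number of arrays limits the precision. Probes were named from reference tables by RefSeq accession (25446 probes), by symbol (5164) or by synonym (682), and 12311 kept the name of the file. A gene symbol was held by 31670 probes, for 16263 symbols.

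Groups followed the labels: tissue, day and exposure, with 4 or 5 arrays each. Slide was read from the array barcode and scan day from the scan date, both in the file headers. The 10 slides each carried 1 tissue and at most 1 array of a group, and slides 1 to 5 were scanned before slides 6 to 10. The tests were limma's moderated tests (lmFit and eBayes, limma 3.58.1 in R 4.3.3, with statmod 1.5.0 and the data.table package 1.17.8), two-sided, with Benjamini-Hochberg adjustment over all probes of a comparison and a threshold of adjusted p 0.05. The 4 groups of a tissue were fitted together with no covariates. The differences between the tissues' exposure effects were fitted on all 37 arrays. The p-values measure the spread between pooled samples. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

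A set of 35 gene lists, 23 of pathways and 12 of cell types, was fixed before the data were examined, as were the comparisons, the tests and the rule for named genes. Each list with at least 5 measured genes was tested with limma's camera at its preset correlation between genes of 0.01, on the brightest probe of each gene, with adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Counts of list members given as "adjusted over the list alone" come from the same gene tests, adjusted within the list.

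Named genes were taken by rule, with the brightest probe of each symbol and without clone or contig names. In each exposure comparison these were the 10 largest rises and 10 largest falls past the threshold, the 12 genes with the smallest unadjusted p where fewer than 10 passed (given as not past the threshold), the 4 members of each called list with the smallest p in the list's direction, and mt2, hmox1a, hsp70l, gclc, sod1, cat, cyp1a, il1b and fabp10a. The gene gstp1 was on the rule as well and had no probe under that symbol. In the other comparisons the rule took the 5 largest rises and falls past the threshold, or the 3 smallest p where fewer than 3 passed. Where no array of a group was well above background for a gene, its fold is given as a lower bound against the background level.

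Alternatives fixed beforehand were quantile normalization, median scaling, the 75th percentile over probes well above background on all arrays, the normexp background method with an offset of 50, the value table, no filter on dim probes and a stricter filter. Others were trend and robust moderation, array quality weights, only the 2 groups compared, all 37 arrays in 1 fit, a slide block, a replicate block, a scan day term, an adjusted p of 0.1, a fold of at least 1.5, the mean over a gene's probes, and leaving out each array in turn. Added after seeing the data were the fits without 9 arrays that stood apart in marker genes, and fits with a marker level as a covariate. An array stood apart when its mean germ cell marker level was over -1 or its hepatocyte marker level under 6 (5 liver arrays), or its level of 5 genes of the posterior intestine was under 0 (4 intestine arrays). That list of posterior intestine genes and the set of major histocompatibility genes were chosen after seeing the data.

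The gene and list tests were run on simulated normalized levels, with each probe drawn independently and 50 probes changed per size. At a log2 change of 1, it recovered 8% of them in liver at day 3, 8% in liver at day 21, 42% in intestine at day 3 and 26% in intestine at day 21. At a log2 change of 2 the shares were 50%, 60%, 66% and 72%, at 3 they were 74%, 82%, 80% and 88%, and at 4 they were 84%, 92%, 94% and 86%. All sizes were planted together, and 114 to 147 probes were called in a comparison, which eases the Benjamini-Hochberg threshold. Where few probes change, the shares would be lower. A list moved by 0.5 on the log2 scale was called in all 4 comparisons, with 0 other lists called. Because the simulated genes were independent, this does not show how often camera calls lists where genes vary together. In other splits of the real arrays the median count of called lists was 12 and 15 in liver at day 3 and day 21. In intestine it was 11 and 13.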

Results

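Gene expression was measured on 37 arrays in 8 groups. Liver was arrayed from 4 control and 5 exposed samples at day 3, and from 4 control and 5 exposed samples at day 21. Intestine was arrayed from 5 control and 5 exposed samples at day 3, and from 5 control and 4 exposed samples at day 21. C1 is the silver dose of 0.1 mg/L, and exposed means fed with nauplii from that dose. Levels are log2 signal relative to each array's 75th percentile, and changes are log2 differences with their standard error (SE). Positions refer to build Zv9.

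The tissue markers differed between liver and intestine. The liver fatty acid binding protein gene fabp10a had a mean of 10.33 to 10.61 in the liver groups and 7.47 ± 3.30 (SD, n = 5) to 8.72 ± 1.09 (SD, n = 5) in the intestine groups. The intestinal fatty acid binding protein gene fabp2 had group means of 6.08 to 7.72 in liver and 8.96 to 9.65 in intestine. Single arrays of the tissues overlapped. The level of fabp2 reached 9.30 on a liver array and fell to 8.40 on an intestine array, both in controls at day 21. That of fabp10a reached 9.98 on an intestine control array at day 21 and fell to 9.88 on a liver control array at day 3. The trypsin gene prss1, a product of the exocrine pancreas, was bright in both tissues, with group means of 8.70 to 10.03 in liver and 9.56 to 10.53 in intestine. Germ cell markers were high on 4 liver arrays, with mean levels of 0.13 in control replicate 5 at day 3, -0.70 and -0.72 in exposed replicates 3 and 5 at day 3, and 0.35 in exposed replicate 2 at day 21. Hepatocyte markers were low in control replicate 4 at day 21, at 5.13.

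The first comparison asks what 3 days of the diet changed in liver. At day 3, mpzl1l, which encodes a cell surface protein of the immunoglobulin superfamily, rose by 4.03 (SE 0.51), 16.3-fold, from -5.42 ± 0.61 (SD, n = 4) to -1.39 ± 1.26 (SD, n = 5), adjusted p = 0.02. It was the 1 probe of 35918 that passed, and 1489 had an unadjusted p under 0.05. The gene (NM_001257340) lies on chromosome 10, and its probe spans 281242 to 281301. It was higher in 20 of 20 pairs of an exposed and a control array. In liver its level moved in steps between groups: 0 of 4 control arrays at day 3 were above -4, and all other liver arrays were. These include the unexposed liver arrays at day 21, at -2.08 ± 0.49 (SD, n = 4). In intestine the steps lay within groups. There 0 of 5 control arrays at day 3, 2 of 5 control arrays at day 21, 3 of 5 exposed arrays at day 3 and 3 of 4 exposed arrays at day 21 were above -4. The gene was thus present or absent on single arrays, as were the histocompatibility genes described below. The difference at day 3 alone does not show an effect of the diet.

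Among the genes not past the threshold in liver at day 3, the hepcidin gene hamp, whose product blocks iron export from cells, differed by -4.64 (SE 0.80), with 0.21 ± 1.69 (SD, n = 5) in exposed and 4.85 ± 0.27 (SD, n = 4) in control samples, adjusted p = 0.173. It was lower in 20 of 20 pairs. The gene slc40a1, which encodes the iron exporter that hepcidin acts on, differed by 2.61 (SE 0.68), adjusted p = 0.776, and was picked out after its values were seen. Of 39 metal handling genes, 2 passed when adjusted over the list alone, 1 up and 1 down, and 0 passed over all genes. That list was not called, adjusted p = 0.254. Others with small p were atp2a2a, a calcium pump gene, at -4.04 (SE 0.64, adjusted p = 0.122), ripk2, a kinase gene of innate immune signalling, at 2.03 (SE 0.37, adjusted p = 0.184), and elovl6, a gene of fatty acid elongation, at 2.85 (SE 0.66, adjusted p = 0.523). The genes glod5, trabd2b, ptgr1.1, sparcl1, mpdu1b, thoc2 and slc18a2 lay between -0.81 and -2.63, with adjusted p from 0.276 to 0.475. The stress genes showed small differences, all at adjusted p = 1: the metallothionein gene mt2 at 0.76, the heat shock gene hsp70l at -0.87, the haem oxygenase gene hmox1a at -0.47, sod1 at 0.29, cat at 0.23, gclc at 0.06, cyp1a at 0.07, il1b at -0.13 and fabp10a at -0.09.

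Camera called 6 of 35 lists in liver at day 3, and 0 of these calls held with an estimated correlation or with fry. Of 60 fatty acid oxidation genes, 50 were higher, with a mean of 0.27 and adjusted p = 2.74e-06. Examples were crot at 1.66 and etfdh at 0.72. Of 87 oxidative phosphorylation genes, 75 were higher (mean 0.16, adjusted p = 0.000201), such as uqcrfs1 at 0.36. Of 53 proteasome genes, 35 were higher (mean 0.16, median 0.07, adjusted p = 0.0137), such as psma5 at 0.67. The immunoproteasome gene psmb9b, at 5.1, lifted this mean: it belongs to a histocompatibility type present or absent on single arrays, and lay at -8.16 and -7.62 on 2 control arrays and -1.04 and -0.48 on the other 2. Of 113 cell cycle genes, 79 were higher (mean 0.22, adjusted p = 0.0147), such as rfc3 at 0.99. Of 42 endoplasmic reticulum stress genes, 35 were lower (mean -0.31, adjusted p = 0.00216), with dnajb9a at -1.12. Of 59 germ cell markers, 37 were lower (mean -0.57, adjusted p = 0.0147), with dnali1 at -2.61, and dmc1, a meiosis gene, at least 5.03-fold lower. For each of these 6 lists the adjusted p = 0.939 with an estimated correlation. Adjusted over the list alone, 1 gene of the endoplasmic reticulum stress list passed, and 0 of the other lists. Within the first and second scan the means had opposite signs for fatty acid oxidation (0.52 and -0.11), oxidative phosphorylation (0.48 and -0.32), cell cycle (-1.04 and 1.96) and germ cell markers (-2.37 and 1.87), and the same sign for endoplasmic reticulum stress (-0.40 and -0.22) and proteasome (0.09 and 0.17). With the normexp background method the direction turned for oxidative phosphorylation (adjusted p 4.67e-05), proteasome (0.000205), fatty acid oxidation (0.478) and cell cycle (0.424). The direction of the cell cycle list turned without exposed replicate 3 or 5 (adjusted p 0.636 and 0.667) and its call ended without control replicate 1, 2 or 3 (0.8, 0.113 and 0.254). Its mean also turned without control replicate 1, to -0.08. For the germ cell list the direction turned without control replicate 5 (0.97) and the call ended without exposed replicate 2 or 4 (0.413 and 0.72). The calls also ended for endoplasmic reticulum stress without control replicate 5 (0.307), for oxidative phosphorylation without exposed replicate 1 (0.0612), and for proteasome without control replicate 2 or 3 or exposed replicate 2 or 5 (0.0613 to 0.278). With single arrays left out, the means ran from 0.16 to 0.42 for fatty acid oxidation, 0.05 to 0.29 for oxidative phosphorylation, 0.08 to 0.24 for proteasome, -0.15 to 0.71 for cell cycle and -1.04 to 0.16 for germ cell markers. Without the arrays high in germ cell or low in hepatocyte markers, the endoplasmic reticulum stress call ended (0.121) and the cell cycle direction turned (0.183).

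Limits at day 3 in liver: with a slide block, mpzl1l differed by 3.99 at adjusted p = 0.155, and by 4.80 and 3.01 within the first and second scan. The call ended without control replicate 1, 2 or 5 or exposed replicate 2, 4 or 5 (adjusted p 0.0529 to 0.151), and other splits of the same arrays gave up to 1072 probes.

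The same question at day 21 concerned 35918 probes in liver. The yolk precursor genes rose together. The gene vtg1, a vitellogenin normally made in female liver under oestrogen, rose by 11.09 (SE 1.53), 2177-fold, from -2.32 ± 1.24 (SD, n = 4) to 8.77 ± 1.80 (SD, n = 5), adjusted p = 0.00696. The other vitellogenin genes did so too: vtg7 by 9.79 (SE 1.41), vtg6 by 9.67 (SE 1.43), vtg4 by 11.45 (SE 1.70), vtg5 by 10.93 (SE 1.67) and vtg2 by 12.66 (SE 2.03), with adjusted p from 0.00696 to 0.0109. The gene nots, for the liver protease nothepsin, rose by 7.27 (SE 1.37), from -4.59 ± 0.15 (SD, n = 4) to 2.68 ± 3.73 (SD, n = 5), adjusted p = 0.0396. Each of these 7 genes was higher in 20 of 20 pairs of arrays. Some further called probes named vtg2, vtg4 or vtg5 carry the description of vtg1. The probes may thus not fully tell these related genes apart. The vtg1 gene (NM_001044897) lies on chromosome 22, where its probe spans 25203737 to 25203796, and nots (NM_131804) on chromosome 14, probe 37891811 to 37891870.

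Fewer genes of other kinds passed in liver at day 21. The gene tram1, whose product helps secreted proteins enter the endoplasmic reticulum, rose by 1.35 (SE 0.26), adjusted p = 0.0476. The gene htatip2, for an oxidoreductase (NM_131681, chromosome 7, probe 17878309 to 17878368), fell by 1.80 on the log2 scale (SE 0.24), from 4.26 ± 0.18 (SD, n = 4) to 2.46 ± 0.38 (SD, n = 5), adjusted p = 0.00696. The gene gsr, for glutathione reductase, fell by 1.38 (SE 0.27), from 2.22 ± 0.45 (SD, n = 4) to 0.84 ± 0.31 (SD, n = 5), adjusted p = 0.0476. In all, 58 probes rose and 5 fell, 53 of them probes of vitellogenin genes, and 3239 had an unadjusted p under 0.05. The 63 probes carried 12 symbols, 9 higher and 3 lower, and the brightest probe of a gene passed for 10 genes. Among the higher symbols was rbp2a, through a probe of a cDNA clone that rose by 11.56 (SE 1.59, adjusted p = 0.00696). The brightest rbp2a probe did not pass. The calls of vtg1, vtg4, vtg5, vtg6, vtg7 and htatip2 held without any single array, that of vtg2 ended without control replicate 3 (adjusted p 0.0579), that of nots held only without exposed replicate 1 or 4, that of tram1 only without control replicate 1, and that of gsr only without control replicate 2 or exposed replicate 4 (adjusted p otherwise up to 0.133, 0.201 and 0.167).

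**Figure D1:**
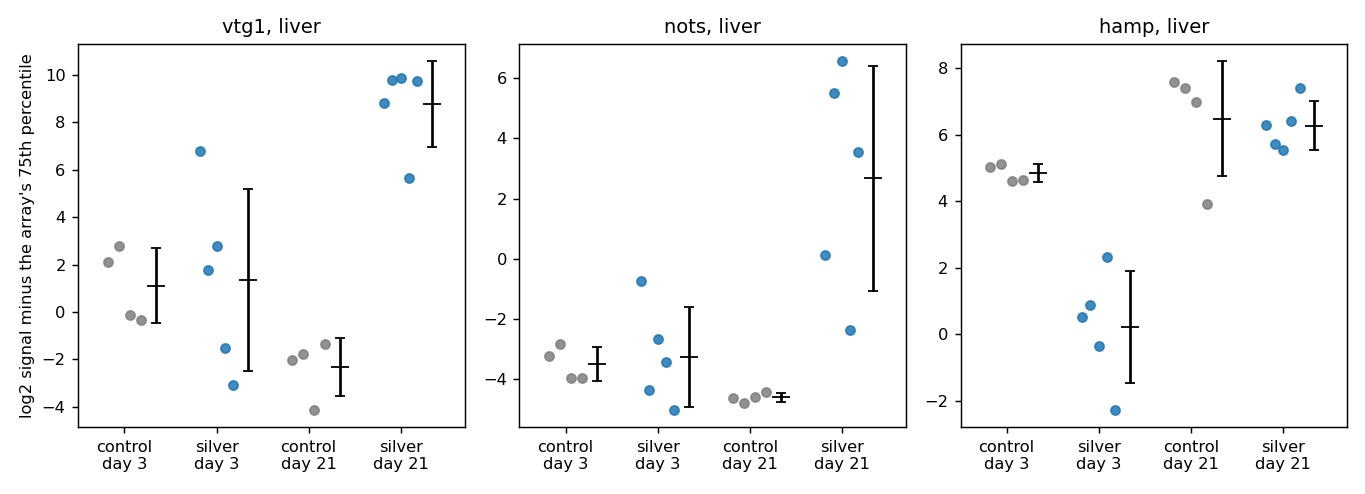
Level of vtg1, nots and hamp on each liver array (log2 signal relative to the array's 75th percentile) by day, grey for control and blue for exposed samples, with bars for the mean ± SD of 4 or 5 arrays. At day 21 the exposed arrays lie above the control arrays for vtg1 and nots, and at day 3 the exposed arrays lie below the control arrays for hamp, where the difference did not pass the threshold.

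Vitellogenin levels differed within groups too. At day 3 vtg1 was at 1.1 ± 1.58 (SD, n = 4) in control and 1.34 ± 3.85 (SD, n = 5) in exposed liver, with 6.77 in exposed replicate 1. At day 21 the 5 exposed livers lay between 5.64 and 9.89 and the 4 control livers between -4.14 and -1.36. In intestine the group means lay between -3.23 and -0.91.

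Camera called 19 of 35 lists in liver at day 21, and 2 of these calls held with an estimated correlation and with fry. The oestrogen-responsive liver list was higher in 18 of 19 genes (mean 5.41, median 3.28, adjusted p = 4.38e-15, and adjusted p = 0.047 with an estimated correlation). Of its genes 10 rose and 1 fell when adjusted over the list alone, and 7 rose over all genes. The oestrogen receptor gene esr1, a member picked out for its function, differed by 2.22, adjusted p = 0.14. The endoplasmic reticulum stress list was higher in 39 of 42 genes (mean 0.66, adjusted p = 1.26e-13, and adjusted p = 0.0471 with an estimated correlation), and 12 of its genes rose when adjusted over the list alone, against 0 over all genes. Its examples were hyou1, a chaperone gene, at 1.86 (SE 0.37, adjusted p = 0.0599), dnajc3a at 1.37 (SE 0.29, adjusted p = 0.0842), the stress sensor gene eif2ak3 at 1.03 (SE 0.22, adjusted p = 0.0938) and dnajb9a at 1.19 (SE 0.26, adjusted p = 0.105). The chaperone gene hspa5 at 1.70 and the transcription factor gene xbp1 at 1.01 were picked out after their values were seen. With a slide block the mean of the oestrogen-responsive list was 5.35 and that of the endoplasmic reticulum stress list 0.68, and within the 2 scans the means were 4.48 and 6.53 for the former and 0.42 and 0.97 for the latter.

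The glutathione and Nrf2-regulated list was lower in 43 of 58 genes in liver at day 21 (mean -0.40, adjusted p = 1.74e-05, but adjusted p = 0.546 with an estimated correlation). Of these, 5 fell when adjusted over the list alone and 1, gsr, over all genes. Further members were the glutathione transferase gene gstt1b at -1.12 (SE 0.24, adjusted p = 0.0842), mgst3b at -0.95 (SE 0.22, adjusted p = 0.139) and the peroxiredoxin gene prdx1 at -2.33 (SE 0.59, adjusted p = 0.196). The metallothionein gene mt2, which binds silver and other metals, differed by -2.46 (SE 0.57), with 3.53 ± 0.81 (SD, n = 5) in exposed and 5.99 ± 1.34 (SD, n = 4) in control samples, adjusted p = 0.131, and it was the 1 gene of the metal handling list that passed when adjusted over the list alone. Of 91 xenobiotic metabolism genes, 64 were lower (mean -0.33, adjusted p = 0.000175, adjusted p = 0.546 with an estimated correlation), with cyp2x9 at -4.19, the bile exporter gene abcc2 at -1.0 and ugt5a2 at least 26.9-fold lower. The other stress genes had adjusted p from 0.47 to 0.965: gclc at -0.94, il1b at 0.93, fabp10a at 0.18, hsp70l at -0.25, cat at 0.19, cyp1a at 0.09, sod1 at -0.07 and hmox1a at -0.08.

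**Figure D2:**
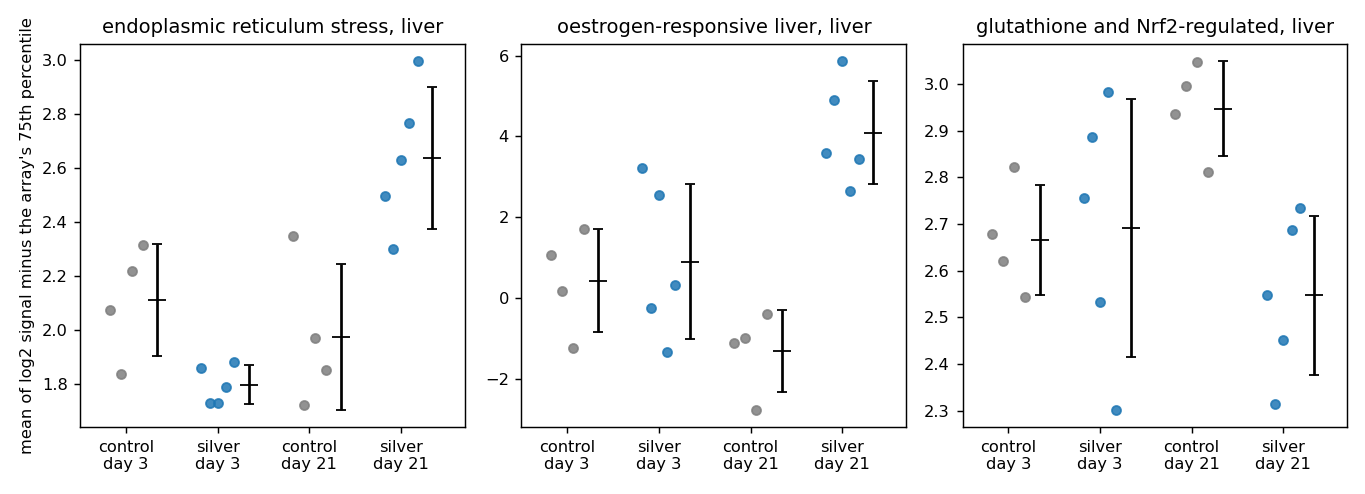
Mean level of the endoplasmic reticulum stress, oestrogen-responsive liver and glutathione and Nrf2-regulated lists on each liver array (log2 signal relative to the array's 75th percentile) by day, grey for control and blue for exposed samples, with bars for the mean ± SD of 4 or 5 arrays. At day 21 the mean change was 0.66 for the first list, 5.41 for the second and -0.40 for the third.

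Markers of other cell types moved in liver at day 21 as well. Of 59 germ cell markers, 55 were higher (mean 1.77, adjusted p = 2.54e-07, adjusted p = 0.546 with an estimated correlation), with the group level at -2.31 ± 1.81 (SD, n = 5) in exposed and -4.09 ± 0.62 (SD, n = 4) in control samples. Without exposed replicate 2, the array high in these markers, the mean was 1.11. The germ line gene piwil1 was at least 7.95-fold higher and the oocyte gene gdf9 at least 2.28-fold higher. Of 19 endocrine pancreas markers, 18 were lower (mean -1.83, adjusted p = 6.29e-07, adjusted p = 0.546 with an estimated correlation). The insulin gene ins, at -3.47 (adjusted p = 0.532), lay at 4.50 ± 4.39 (SD, n = 5) in exposed and 7.97 ± 0.98 (SD, n = 4) in control samples. Of 21 goblet and enteroendocrine markers, 20 were lower (mean -1.58, adjusted p = 1.74e-05, adjusted p = 0.546 with an estimated correlation). Hepatocyte markers were higher in 36 of 37 genes (mean 0.56, adjusted p = 9.51e-05, adjusted p = 0.855 with an estimated correlation), and without control replicate 4, the array low in these markers, the direction turned (adjusted p 0.499). Cell cycle genes were higher in 106 of 113 (mean 1.04, adjusted p = 4.61e-12, adjusted p = 0.643 with an estimated correlation), with a mean of 0.64 without exposed replicate 2. Without exposed replicate 5 the means of the endocrine pancreas and the goblet and enteroendocrine markers were -1.08 and -0.95.

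Limits at day 21 in liver: without the 5 liver arrays that stood apart in germ cell or hepatocyte markers, 1 probe passed, none of the 63, while the 6 vitellogenin genes differed by 9.68 to 12.41 at adjusted p 0.0524 to 0.0956, and with only the 2 groups compared 3 probes passed, all among the 63, with vtg1 at adjusted p = 0.0212, the other vitellogenin genes and htatip2 at 0.055 to 0.0712, and nots, tram1 and gsr at 0.287 to 0.354. The count was 39 without control replicate 2, and larger with all 37 arrays in 1 fit (189) and with array quality weights (242). With a slide block 29 probes passed, all among the 63, with vtg1 at 11.13 (adjusted p = 0.0216), htatip2 at -1.84 (0.0257), vtg2 at 12.48 (0.0688), nots at 7.16 (0.212), tram1 at 1.36 (0.283) and gsr at -1.38 (0.212), and within the first and second scan vtg1 differed by 9.76 and 12.77, htatip2 by -1.76 and -1.86, nots by 5.59 and 9.74, and gsr by -1.58 and -1.20.

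In intestine at day 3, where the diet first meets the tissue, limma called 0 of 36400 probes, with 1774 at an unadjusted p under 0.05. The smallest p belonged to ypel3, at 1.31 (SE 0.23), with 2.78 ± 0.45 (SD, n = 5) in exposed and 1.47 ± 0.47 (SD, n = 5) in control samples, adjusted p = 0.749. The same adjusted p held for the next genes. These were shcbp1 at -1.49 (SE 0.31), sfxn5b at -1.31 (SE 0.29), the folate pathway gene mthfd2 at -1.16 (SE 0.26), trib3, a gene of the amino acid stress response, at -0.64 (SE 0.15), and aanat2, the melatonin synthesis gene, at -4.46 (SE 1.12). The chemokine receptor gene ccr9b was at 1.06 (SE 0.26), and slc25a38b, ehd4, imp4 and rgcc lay between -0.89 and -1.40, while fhad1 was at least 2.83-fold lower. The metallothionein gene mt2 differed by -0.00 (SE 0.53), cat by 0.47, sod1 by 0.25, hsp70l by -0.20, gclc by -0.07, fabp10a by -0.40, il1b by -0.14, hmox1a by -0.13 and cyp1a by -0.01, with adjusted p from 0.993 to 1.

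Camera called 7 lists in intestine at day 3, and 0 of these calls held with an estimated correlation or with fry. Of 30 exocrine pancreas markers, 27 were lower (mean -0.47, adjusted p = 0.000214, adjusted p = 0.977 with an estimated correlation), with prss1 at -0.69 and ela2 at -0.89. Of 31 nervous and swim bladder markers, 23 were lower (mean -0.29, adjusted p = 0.00426, adjusted p = 0.977 with an estimated correlation), such as nos1 at -0.77. Enterocyte markers were lower in 29 of 48 genes (mean -0.50, median -0.05, adjusted p = 0.039, adjusted p = 0.977 with an estimated correlation), with the peptidase gene enpep at -0.89 and the amino acid transporter gene slc6a19b at -1.67. Goblet and enteroendocrine markers were lower in 13 of 21 (mean -0.19, adjusted p = 0.0278, adjusted p = 0.851 with an estimated correlation), with the hormone gene insl5a at -1.66. Fatty acid oxidation genes were higher in 44 of 62 (mean 0.15, adjusted p = 0.0202), oxidative phosphorylation genes in 71 of 87 (mean 0.08, adjusted p = 0.0383) and germ cell markers in 35 of 55 (mean 0.66, adjusted p = 0.0202), each with adjusted p = 0.977 with an estimated correlation. The direction of the oxidative phosphorylation list turned without exposed replicate 2 (adjusted p 0.756), and its call ended without control replicate 1, 2 or 3 or exposed replicate 5 (0.0891 to 0.957). Its mean also turned without control replicate 3, to -0.009. The other calls ended as well: exocrine pancreas without control replicate 5 or exposed replicate 3 (0.0566 and 0.11), nervous and swim bladder without exposed replicate 2 (0.13), goblet and enteroendocrine without control replicate 1 or 4 or exposed replicate 2 (0.0586 to 0.0883), and fatty acid oxidation without control replicate 1 or 3 or exposed replicate 2 or 3 (0.0598 to 0.11). Enterocyte markers lost the call without control replicate 1, 2 or 3 or exposed replicate 1, 2 or 5 (0.0695 to 0.385), and germ cell markers without control replicate 1, 4 or 5 or exposed replicate 3 or 5 (0.0586 to 0.443). Within the 2 scans the means had opposite signs for oxidative phosphorylation (0.27 and -0.04) and exocrine pancreas markers (0.43 and -1.06). With single arrays left out, the means ran from -0.02 to 0.20 for oxidative phosphorylation, -0.74 to -0.18 for exocrine pancreas, -0.31 to -0.06 for goblet and enteroendocrine and 0.29 to 1.17 for germ cell markers. Without the 4 arrays low in genes of the posterior gut, 3 of them exposed samples at day 3, the enterocyte call ended (0.515), as did those of nervous and swim bladder (0.657), germ cell (0.383), goblet and enteroendocrine (0.115) and fatty acid oxidation genes (0.0512), and the direction of oxidative phosphorylation turned (6.8e-05). That fit kept only exposed replicates 1 and 3 at day 3. With all arrays, 1 goblet and enteroendocrine gene fell and 0 members of the other 6 lists passed when adjusted over the list alone.

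The intestine samples differed in the genes of the posterior gut, a list of 5 genes chosen after seeing the data. Its mean level was 4.72 ± 1.17 (SD, n = 5) in controls at day 3, 0.0458 ± 5.13 (SD, n = 5) in exposed samples at day 3, 3.99 ± 3.77 (SD, n = 5) in controls at day 21 and 5.16 ± 0.45 (SD, n = 4) in exposed samples at day 21. The level was under 0 in 3 of 5 exposed samples at day 3 (replicates 2, 4 and 5), in control replicate 4 at day 21 and in 0 of the 9 arrays of the other groups. The bile acid binding gene fabp6 lay at -1.43 to 0.60 on these 4 arrays and 7.41 to 9.59 on the other 15, and the bile acid transporter gene slc10a2 at -8.54 to -6.10 against 3.13 to 5.89. In liver, fabp6 was over 0 on 7 of 18 arrays, unevenly between groups. The posterior gut level was under 0 on 1 of 4 control and 3 of 5 exposed liver arrays at day 3. At day 21 it was under 0 on 3 of 4 control and 4 of 5 exposed liver arrays. The liver comparisons at day 3 and over time thus also differ in gut genes, which the liver fits without arrays that stood apart did not screen. Without the 4 arrays, 5 probes passed in intestine at day 3, where only exposed replicates 1 and 3 remained.

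**Figure D3:**
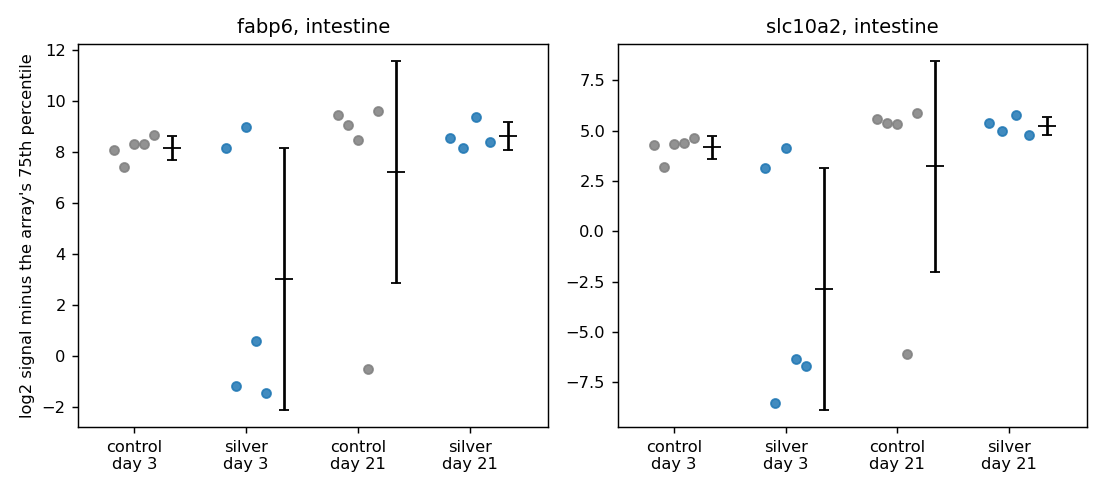
Level of fabp6 and slc10a2 on each intestine array (log2 signal relative to the array's 75th percentile) by group, grey for control and blue for exposed samples, with bars for the mean ± SD of 4 or 5 arrays. The 4 low arrays, 3 of them exposed samples at day 3, lie at or under 0.60 for fabp6 and at or under -6.10 for slc10a2.

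In intestine at day 21, limma called 0 of 36400 probes, with 2122 at an unadjusted p under 0.05. The smallest p among named genes belonged to nod1, a sensor of bacterial cell walls, at 0.78 (SE 0.17), with -2.66 ± 0.21 (SD, n = 4) in exposed and -3.44 ± 0.23 (SD, n = 5) in control samples, adjusted p = 0.846. The same adjusted p held for the kinase gene vrk2 at -0.98 (SE 0.22), pcdh1g32 at 0.81 (SE 0.18), the DNA repair gene xpc at -0.69 (SE 0.18), btr29 at -3.60 (SE 0.92) and trim35-14 at -5.85 (SE 1.49). The genes lrrc41, pargl, tspan13a and tmem168a lay at 0.90, -0.80, -0.71 and -1.60, cbln20 was at least 1.88-fold higher, and spp1 was at least 2.57-fold lower. The metallothionein gene mt2 differed by -1.45 (SE 0.56), with 3.98 ± 0.29 (SD, n = 4) in exposed and 5.43 ± 1.06 (SD, n = 5) in control samples, adjusted p = 0.846, and was lower in 20 of 20 pairs. The other stress genes lay between -0.24 (gclc) and 0.23 (il1b), with hsp70l at 0.22, hmox1a at 0.20, cat at 0.17, sod1 at 0.04, cyp1a at -0.06 and fabp10a at -0.12, at adjusted p from 0.897 to 0.996.

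Camera called 4 lists in intestine at day 21, all higher, and 0 of these calls held with an estimated correlation or with fry. Of 42 endoplasmic reticulum stress genes, 30 were higher (mean 0.29, adjusted p = 0.000482), with the chaperone gene hsp90b1 at 0.87, pdia4 at 1.05, dnajc3a at 0.78 and eif2ak3 at 0.62. Of 19 endocrine pancreas markers, 17 were higher (mean 0.81, adjusted p = 0.000908), such as the somatostatin gene sst1.1 at 2.25. Without control replicate 2 the mean of these markers was 0.48. Cell cycle genes were higher in 95 of 114 (mean 0.29, adjusted p = 0.00674) and oxidative phosphorylation genes in 71 of 87 (mean 0.13, adjusted p = 0.0425). For each of these lists the adjusted p = 0.977 with an estimated correlation, and 0 members passed when adjusted over the list alone. The direction of the oxidative phosphorylation list turned without exposed replicate 3 (adjusted p 0.974), and its means within the 2 scans were -0.26 and 0.31. The call of the endoplasmic reticulum stress list ended without control replicate 1 (0.116), and that of the cell cycle list without control replicate 1 or 4 or exposed replicate 3 (0.299, 0.737 and 0.419) or without the arrays low in posterior gut genes (0.784).

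Whether the effect differed between days was tested as the exposure effect at day 21 minus that at day 3. In liver limma called 0 probes, with 2194 at an unadjusted p under 0.05. The genes with the smallest p were dnajb9a, a cochaperone gene, at 2.32 (SE 0.37), the phosphatase gene ppm1kb at -1.46 (SE 0.28) and vtg7 at 10.30 (SE 1.99), each at adjusted p = 0.192. As a list, the endoplasmic reticulum stress genes differed between days in liver, with a mean difference of 0.98, adjusted p = 2.87e-16 and adjusted p = 0.0421 with an estimated correlation, and 14 of 42 had a larger effect at day 21 than at day 3 when adjusted over the list alone. That difference holds both the higher day 21 mean (0.66) and the lower day 3 mean (-0.31), as for dnajb9a (1.19 and -1.12). The oestrogen-responsive list differed by a mean of 4.94, with adjusted p = 1.95e-10 and adjusted p = 0.0912 with an estimated correlation. In intestine 0 probes passed and 1155 had an unadjusted p under 0.05. The smallest p were those of nod1 at 1.16 (SE 0.23, adjusted p = 0.79), nr0b2a, a repressor gene of bile acid synthesis, at -4.91 (SE 0.99, adjusted p = 0.881) and ethe1, a sulphide oxidation gene, at 1.19 (SE 0.25, adjusted p = 0.889). Without liver exposed replicate 4 at day 21 the liver count became 47, without exposed replicate 1 at day 3 it became 31, and without exposed replicate 3 at day 3 it became 1. It was 93 with all 37 arrays in 1 fit and 182 with array quality weights.

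Whether the effect differed between tissues was tested at each day. At day 21, 39 of 35100 probes had a larger change in liver than in intestine and 0 a smaller one, with 1268 at an unadjusted p under 0.05. They were 37 probes of vitellogenin genes and 2 of nots. The differences were 9.75 (SE 1.62) for vtg6, 11.51 (SE 2.04) for vtg4, 8.86 (SE 1.63) for vtg5, 10.57 (SE 2.00) for vtg1 and 7.97 (SE 1.51) for nots, with adjusted p from 0.0104 to 0.0132. The liver marker fabp10a was bright in exposed intestine at day 21 too, at 8.66 ± 1.12 (SD, n = 4), against 10.61 ± 0.12 (SD, n = 5) in exposed liver. The level of vtg1 in that intestine group was -2.71 ± 1.66 (SD, n = 4). The test thus does not set liver cells against tissue without them. In intestine at day 21 the oestrogen-responsive list was not called, with 11 of 18 genes higher (mean 1.43, median 0.17, adjusted p = 0.0642). Its level did not overlap between exposed (-1.52 ± 0.32, SD, n = 4) and control arrays (-2.95 ± 0.44, SD, n = 5), from which it follows that the exposed array was higher within 4 of 4 slides. Between the tissues that list differed by a mean of 3.65 (adjusted p = 2.26e-14, adjusted p = 0.0191 with an estimated correlation), with a larger change in liver for 12 of 18 genes. With a slide block vtg6 had an adjusted p of 0.0297, vtg5 of 0.0839 and nots of 0.103. At day 3, limma called 0 probes, with 566 at an unadjusted p under 0.05, and the smallest p were those of the heart myosin gene myl7 at -5.32, sparcl1 at -1.88 and dnajb9a at -1.11, each at adjusted p = 1.

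The control samples at day 21 against day 3 give the change without silver. In intestine 14 probes rose and 33 fell, and 2736 had an unadjusted p under 0.05. The genes with the largest changes included regulators of the circadian clock. The clock repressor genes nr1d4b and nr1d4a rose by 5.78 (SE 0.46), from -7.50 ± 1.19 (SD, n = 5) to -1.71 ± 0.61 (SD, n = 5), adjusted p = 8.02e-06, and by 4.51 (SE 0.39), adjusted p = 4.19e-05. At day 3 nr1d4b was well above background on 1 of 5 control arrays and nr1d4a on 4 of 5, so that the size of the rise is uncertain, above all for nr1d4b. With the normexp background method they differed by 1.5 (adjusted p = 0.321) and 1.89 (adjusted p = 0.129). The period gene per2 fell by 1.82 (SE 0.20, adjusted p = 0.000456) and the cryptochrome gene cry1b by 2.04 (SE 0.24, adjusted p = 0.000845), while cry3b rose by 1.42 (SE 0.25, adjusted p = 0.0333). Other genes that rose were cbln7 by 2.76 (SE 0.46, adjusted p = 0.0262) and ilf3b by 0.88 (SE 0.17, adjusted p = 0.0484). Those that fell were csad, a gene of taurine synthesis, by 3.19 (SE 0.51, adjusted p = 0.0214), stra6l, for a retinol transporter, by 1.41 (SE 0.24, adjusted p = 0.0276), and ebp, for an enzyme of cholesterol synthesis, by 1.42 (SE 0.26, adjusted p = 0.0461). Limits in control intestine: the 47 probes became 6 with normexp, 7 with only the 2 groups compared, and 11 to 20 without control replicate 1, 2, 3 or 5 at day 3 or 2, 3 or 5 at day 21. The call of per2 held in every alternative, while those of ebp and ilf3b ended with a slide block (adjusted p = 0.101 for each) and those of cry1b, cry3b, cbln7, csad, stra6l, ebp and ilf3b with normexp (0.0814 to 1) and with only the 2 groups (0.0638 to 0.265).

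In control liver 4 probes rose from day 3 to day 21, those of nr1d4b and cry3b and 2 of zgc:162154, and 1725 had an unadjusted p under 0.05. The count became 4284 with array quality weights, 15 with all 37 arrays in 1 fit, 1 with only the 2 groups compared or with normexp, 0 with a slide block, and 2 and 1 without control replicates 1 and 5 at day 3. The gene nr1d4b rose by 5.91 (SE 0.65, adjusted p = 0.00286), at least 17.4-fold, and cry3b by 2.26 (SE 0.29, adjusted p = 0.00669), from 0.57 ± 0.32 (SD, n = 4) to 2.83 ± 0.45 (SD, n = 4). The gene mpzl1l differed by 3.34 (SE 0.54), adjusted p = 0.0824. The nr1d4b gene (ENSDART00000082475) lies on chromosome 11, where its probe spans 1911224 to 1911283, and per2 (NM_182857) lies on chromosome 2, probe 48424815 to 48424874. The circadian clock list of 46 genes in intestine had a median of -0.17 and a mean of 0.00, with 7 genes past the threshold over all genes and 14 when adjusted over the list alone, 5 up and 9 down (camera down, adjusted p = 0.00808, adjusted p = 0.861 with an estimated correlation). With a slide block nr1d4b differed by 5.98 in liver at adjusted p = 0.0664 and by 5.78 in intestine at adjusted p = 6.28e-05, and cry3b had an adjusted p of 0.0968 in liver and 0.0703 in intestine. With the normexp background method nr1d4b differed by 1.67 in liver at adjusted p = 1.

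**Figure D4:**
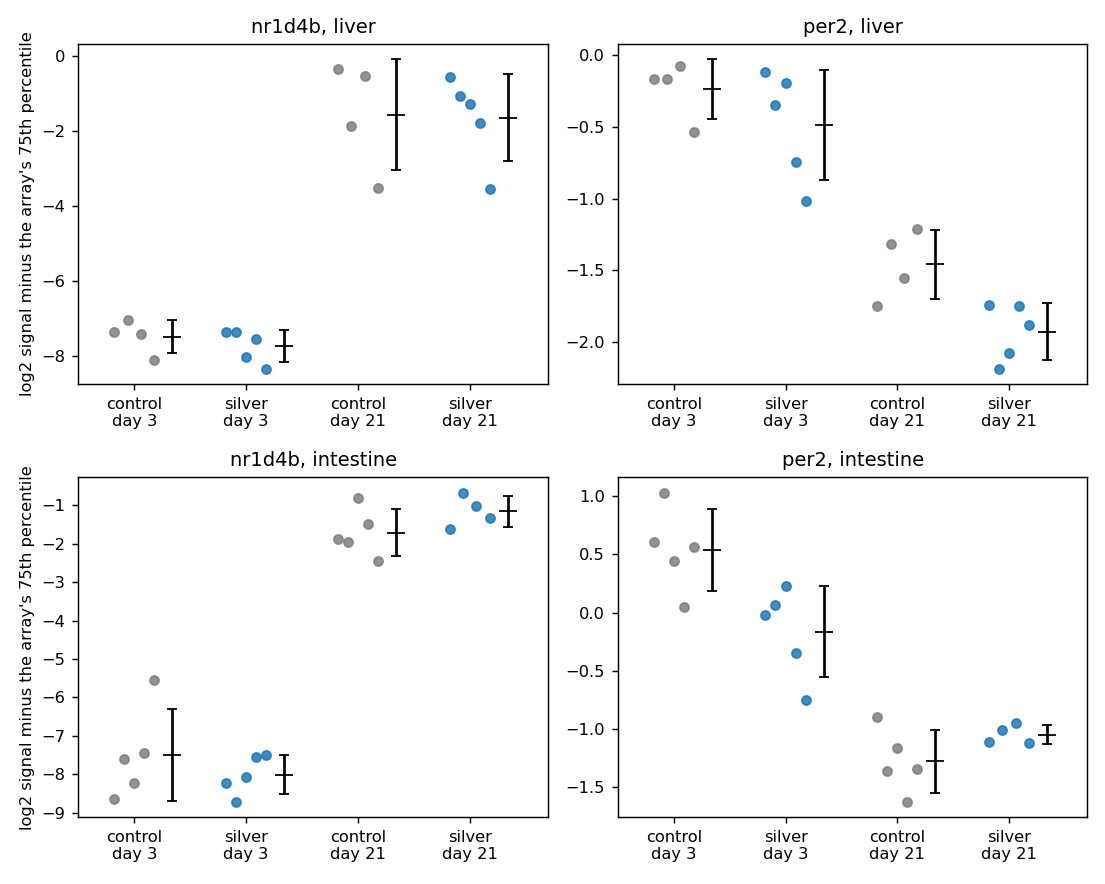
Level of nr1d4b and per2 on each array of liver and intestine (log2 signal relative to the array's 75th percentile) by day, grey for control and blue for exposed samples, with bars for the mean ± SD of 4 or 5 arrays. In control intestine nr1d4b rose by 5.78 and per2 fell by 1.82 from day 3 to day 21.

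Genes of the major histocompatibility complex, chosen after seeing the data, were present or absent on single arrays. Counting a level over -4 as present, the 3 gene types, marked by psmb8f, mhc1uba and mhc1uea, were never all present on an intestine array: 9 arrays had 1 type and 10 had 2. Between absent and present psmb8f there was a gap from -7.44 to 3.02 in intestine. Some absent values of the other markers lay nearer the threshold. The level of mhc1uea was -4.58 in control replicate 3 at day 3, beside psmb8f at 3.02 and mhc1uba at 5.95. In exposed replicates 1 and 3 at day 21, mhc1uba lay at -5.28 and -5.12 with the other markers present. A somewhat lower threshold would count all 3 types on such arrays, so that the intestine count rests on the threshold too. On liver arrays all 3 were over -4 in 16 of 18, but that count rests on where the threshold was placed, since psmb8f lay between -3.22 and 1.83 on these 16, all inside the intestine's gap. The type of mhc1uea was present on 8 of 9 exposed and 2 of 10 control intestine arrays (Fisher's exact test, p = 0.00548, not adjusted for picking this type of the 3 after the data were seen), with the higher share in exposed arrays on 5 of 5 slides. The type of mhc1uba was present on 4 of 9 exposed and 9 of 10 control arrays, and that of psmb8f on 4 of 9 and 2 of 10.

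**Figure D5:**
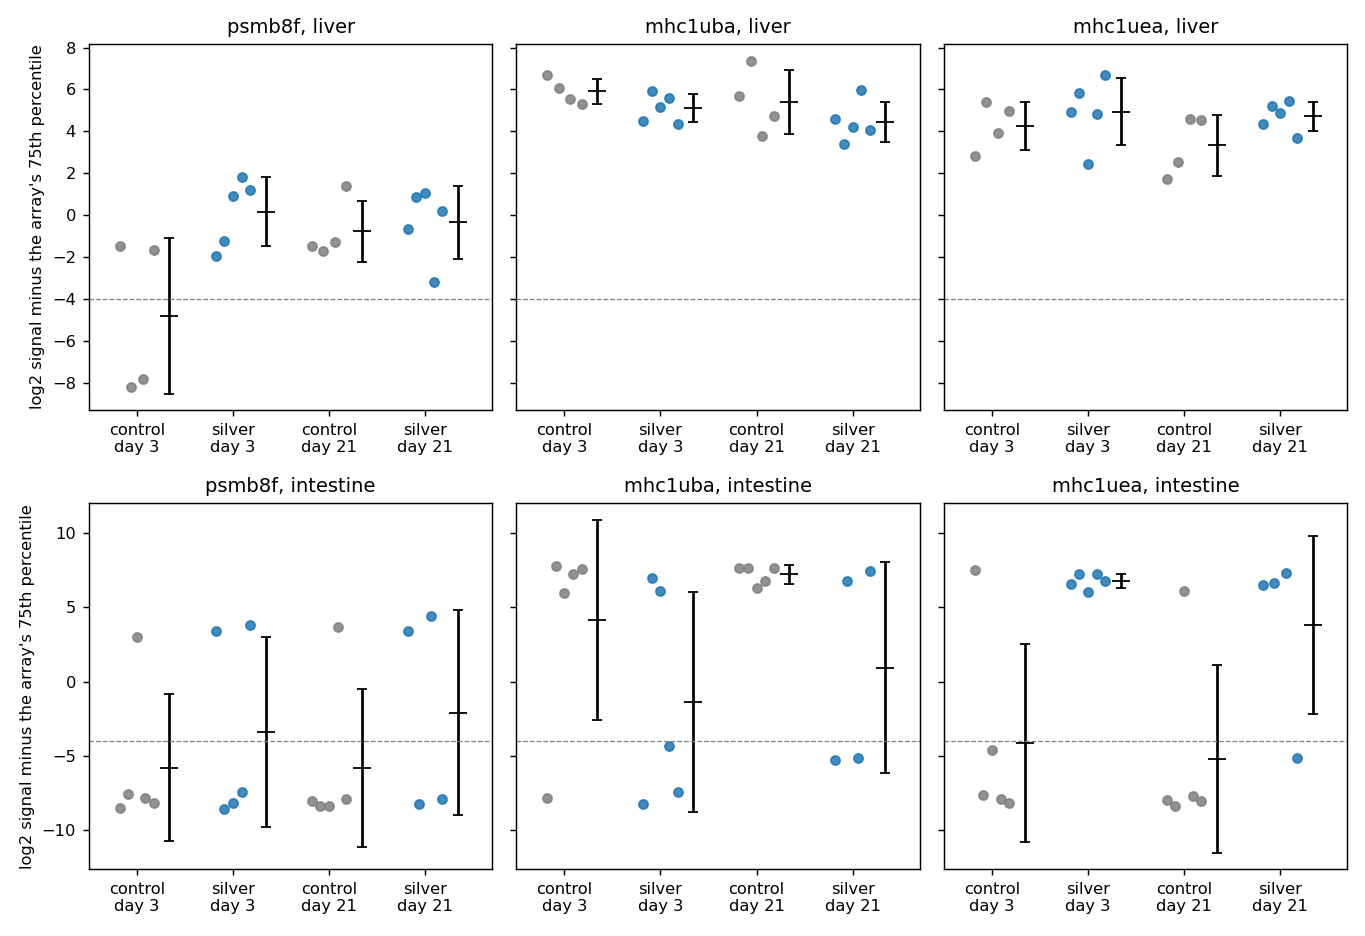
Level of psmb8f, mhc1uba and mhc1uea on each liver and intestine array (log2 signal relative to the array's 75th percentile), grey for control and blue for exposed samples, with a dashed line at -4, above which a gene was counted as present. No intestine array has all 3 genes above the line, and 16 of 18 liver arrays do, 9 of them with psmb8f under 0.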

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

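The tests of female fish, ovary RNA and slide for the vitellogenin genes were chosen after the result was seen, and the splits of the arrays and the search for far values were fixed before the data were examined.

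The exposure effect differed between liver and intestine at day 21 by a test of the difference itself. On the log2 scale it was larger in liver by 10.57 for vtg1, 11.51 for vtg4, 8.86 for vtg5, 9.75 for vtg6 and 7.97 for nots. The intestine samples held RNA of liver markers as well, so that the test does not compare tissues with and without liver cells. With a slide block the calls of vtg1, vtg4 and vtg6 held (adjusted p = 0.0381, 0.0297 and 0.0297), and those of vtg5 (0.0839) and nots (0.103) ended, as did that of nots with normexp (0.157). The oestrogen-responsive liver list differed between the tissues at day 21 with adjusted p = 0.0191 with an estimated correlation. The endoplasmic reticulum stress list differed between the days in liver with adjusted p = 0.0421 with an estimated correlation.

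The rise of 6 vitellogenin genes and nots in exposed liver at day 21 had a median of 10.93 over the 7 genes. Ovary RNA in the exposed samples is argued against as the whole source: with the germ cell marker level as a covariate the median was 10.76 (median SE 1.72), while the call of nots ended (7.27, SE 1.37, became 6.95, SE 1.52, adjusted p = 0.126). A slide is argued against as well, since the smallest median of the 7 genes within a slide was 6.84. Female fish among the exposed pools could not be told apart from an oestrogen-like response in males. Both raise the other oestrogen-responsive genes, which were higher in 11 of 12 with a mean of 2.5. The labels give all fish as male. At day 3 the oocyte gene zp3 was nevertheless at 8.22 in control replicate 5 and 8.28 in exposed replicates 3 and 5. On these arrays vtg1 was at -0.34, 2.77 and -3.08. At day 21 zp3 lay at 4.78, 3.06, 5.74 and 5.67 in exposed replicates 1 to 4, above all controls (0.63, 1.62, -3.95 and 2.49). In exposed replicate 5 at day 21 zp3 was at -1.96, with vtg1 at 9.74. An effect of the silver diet itself remains open beside female fish among the pools. Hepatocyte markers lay at 4.56 ± 1.52 (SD, n = 4) in exposed intestine at day 21, at lowest 2.80. There vtg1 lay between -5.01 and -1.35, as in control intestine (-5.07 to -1.35). If both organs came from the same fish, these values argue against a rise in all exposed fish. Whether they did was not tested, and the values do not separate the 2 explanations.

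Single arrays lay far from the others of their group in 33 of 505 pairs of gene and group (6.53%), where chance gives about 1 in 20 groups (5%). The value is the gap to the nearest array divided by the group's range. In control liver at day 3 it was 0.867 for cat, 0.87 for ptgr1.1 and 0.883 for ripk2, and in exposed liver at day 3 it was 0.864 for mpzl1l and 0.722 for thoc2. In control liver at day 21 it was 0.865 for apoa2, 0.872 for ccnf, 0.903 for cp, 0.895 for gsr, 0.838 for hmox1a, 0.968 for rplp1, 0.862 for rps10, 0.891 for serpina1 and 0.83 for vtg5. In exposed liver at day 21 it was 0.743 for cyp11c1, 0.758 for fabp10a, 0.71 for piwil1, 0.724 for sod1, 0.883 for tdrd7a, 0.937 for tram1 and 0.744 for vtg1. In control intestine at day 3 it was 0.798 for dmrt1, 0.72 for mep1a.2, 0.847 for mthfd2, 0.722 for trib3 and 0.845 for nr0b2a, and in exposed intestine at day 3 it was 0.803 for fabp10a, 0.849 for slc6a19b and 0.752 for sod1. In control intestine at day 21 it was 0.855 for eif2ak3, 0.726 for gclc and 0.71 for nr1d4a, and in exposed intestine at day 21 it was 0.884 for hsp90b1. Of these, 6 came from liver control replicate 4 at day 21 and 4 from liver exposed replicate 2 at day 21.

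Other splits of the same arrays into groups of the same sizes were drawn, 100 per comparison or all 35 for the liver controls. For the controls over time fewer than 5 in 100 splits were as large, the limit fixed beforehand. This makes chance less likely but does not exclude it. In liver 4 probes stood against at most 1 in another split (1 of 35 splits as large, the real one included, the smallest share possible). In intestine 42 probes, counted on probes complete on all arrays, stood against at most 102 (3 of 100). That limit was not met for liver at day 3 (1 probe, highest other 1072, 11 of 100 as large), liver at day 21 (63, highest other 301, 5 of 100) and the tissue difference at day 21 (39, highest other 58, 5 of 100), so that chance was not excluded there either. Where 0 probes were called every split is as large (100 of 100), so that the splits say nothing on chance: intestine at day 3 (highest other 398) and day 21 (57), the day difference in liver (4154) and intestine (2), and the tissue difference at day 3 (811). Chance was not excluded for the lists called at the preset correlation, 6 in liver at day 3 (highest other 19, 92 of 100 as large), 19 in liver at day 21 (22, 18 of 100), 7 in intestine at day 3 (18, 94 of 100) and 4 in intestine at day 21 (21, 98 of 100). With an estimated correlation, a count without a written prediction, 2 lists were called in liver at day 21, endoplasmic reticulum stress and oestrogen-responsive, against at most 1 in another split (1 of 100 as large, the real one included). This makes chance less likely but does not exclude it. Splits that call 301, 398, 811, 1072 or 4154 probes point to a structure of the samples, and which one was not tested.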

How the results depend on the processing

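The fits without the arrays that stood apart and those with a marker level as a covariate were chosen after seeing the data, and all other alternatives were fixed before. Of 7684 values under another setting, 7037 kept their direction and side of the threshold or, for a count, stayed within 1.5-fold. The oestrogen-responsive and endoplasmic reticulum stress lists in liver at day 21 were called under all 10 alternatives run for them. The gene vtg1 lost its call under 1 of 17 (adjusted p = 0.0524 without the arrays that stood apart), htatip2 under 2, nots under 8, and tram1 and gsr under 9 each, with the direction kept. Where the values below moved or turned, the cause was not tested. None of the single genes whose sign turned passed the threshold in either setting. Signal over background limits dim genes: normexp, which lifts dim signals, moved the median of all genes by 0.344 in liver at day 3, by -0.370 for the day difference in liver and by 0.354 for the tissue difference at day 3. Median scaling moved it by 0.124, -0.145 and 0.125 for liver at day 3, the day difference in liver and control liver over time, and quantile normalization by -0.127 and the value table by -0.130 for the day difference in liver.

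With quantile normalization the count of probes was 2 for liver day 3. The direction turned for the ribosomal proteins list in liver day 21 (0.793), with the adjusted p in brackets. The sign turned for cyp1a -0.15 and il1b 0.12 in liver day 3, cat -0.36, cyp1a -0.25 and fabp10a -0.17 in liver day 21. With the value table the count of probes was 2 for liver day 3. The direction turned for the ribosomal proteins list in liver day 21 (0.789), with the adjusted p in brackets. Signs turned for cyp1a -0.15 and il1b 0.12 in liver day 3, cat -0.36, cyp1a -0.25 and fabp10a -0.17 in liver day 21. With median scaling the sign turned for fabp10a 0.0321 in liver day 3, cyp1a 0.0316 and mt2 0.0345 in intestine day 3. With normexp and an offset of 50 the count of probes was 1 for control liver over time and 6 for control intestine over time. The count of lists was 18 for liver day 3. The direction turned for the fatty acid oxidation list in liver day 3 (0.478), the oxidative phosphorylation list in liver day 3 (4.67e-05), the proteasome list in liver day 3 (0.000205) and the cell cycle list in liver day 3 (0.424), with the adjusted p in brackets. There the sign turned for cat -0.13, cyp1a -0.26, gclc -0.19, il1b 0.58 and sparcl1 0.55 in liver day 3, cyp1a 0.0377 and il1b 0.0475 in intestine day 3, il1b -0.14 in intestine day 21, sparcl1 0.62 in the tissue difference at day 3.

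At an adjusted p under 0.1 the count of probes was 101 for liver day 21 and 89 for control intestine over time. With all 37 arrays in 1 fit the count of probes was 189 for liver day 21, 2 for intestine day 21, 93 for the day difference in liver, 15 for control liver over time and 18 for control intestine over time. With only the 2 groups compared the count of probes was 0 for liver day 3, 3 for liver day 21, 7 for intestine day 21, 1 for control liver over time and 7 for control intestine over time. With array quality weights the count of probes was 34 for liver day 3, 242 for liver day 21, 182 for the day difference in liver, 4284 for control liver over time, 84 for control intestine over time and 60 for the tissue difference at day 21. It also turned the sign of cat -0.44, cox11 -0.0516 and cyp1a -0.82 in liver day 21, hmox1a 0.0179, il1b 0.0391 and mt2 0.00509 in intestine day 3, cyp1a 0.10, fabp10a 0.0555 and hmox1a -0.0581 in intestine day 21. With a scan day term the sign turned for cyp1a 0.0179 in intestine day 21. With a slide block the count of probes was 0 for liver day 3, 29 for liver day 21, 0 for control liver over time, 21 for control intestine over time and 20 for the tissue difference at day 21. The count of lists was 4 for intestine day 3. The sign changed for cyp1a 0.0814, fabp10a 0.0492 and hmox1a -0.0304 in intestine day 21.

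With an estimated correlation between genes the count of lists was 0 for liver day 3, 2 for liver day 21, 0 for intestine day 3 and 0 for intestine day 21. With fry the count of lists was 0 for liver day 3, 2 for liver day 21, 0 for intestine day 3 and 0 for intestine day 21.

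With a replicate block the count of probes was 0 for liver day 3, 2 for control liver over time and 22 for control intestine over time. Signs changed for gclc -0.0141 in liver day 3, hmox1a 0.00838 in liver day 21, fabp10a 0.15 in intestine day 21. The numbers share only a number across groups: residuals of arrays with the same number correlated between -0.560 and 0.569 in liver (9 of 24 pairs over 0.1) and between -0.250 and 0.344 in intestine (8 of 27), and 5 of 18 and 6 of 19 arrays correlated best with an array of their own number.

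Without the arrays that stood apart the count of probes was 3 for liver day 3, 1 for liver day 21, 5 for intestine day 3 and 1 for intestine day 21. For intestine day 3 only exposed replicates 1 and 3 remained. The count of lists was 10 for liver day 3. The direction turned for the cell cycle list in liver day 3 (0.183), the hepatocyte markers list in liver day 21 (0.972) and the oxidative phosphorylation list in intestine day 3 (6.8e-05), with the adjusted p in brackets. There the sign changed for fabp10a 0.00647 and hmox1a 0.00459 in liver day 3, cat -0.15 and cyp1a -0.48 in liver day 21, fabp10a 1.18, hmox1a 0.93, mt2 1.01 and sod1 -0.0128 in intestine day 3, cyp1a 0.19, fabp10a 0.16, hmox1a -0.29 and il1b -0.20 in intestine day 21. With the germ cell marker level as a covariate the count of probes was 5 for liver day 3. The sign turned for cyp1a -0.0663 and gclc -0.0105 in liver day 3, hmox1a 0.27, hsp70l 0.0453 and sod1 0.26 in liver day 21, il1b 0.10 and mt2 0.0211 in intestine day 3, fabp10a 0.00496 in intestine day 21. With the hepatocyte marker level as a covariate the count of probes was 7 for liver day 3. Signs turned for cat -0.26 and cyp1a -0.45 in liver day 21, cyp1a 0.00303 and mt2 0.00502 in intestine day 3. With the posterior intestine level as a covariate the sign turned for fabp10a 0.35, hmox1a 0.95, il1b 0.24, mt2 0.34 and sod1 -0.0467 in intestine day 3, cyp1a 0.0263 and hmox1a -0.0741 in intestine day 21.

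Leaving out each array in turn gave counts of 0 to 3 for liver day 3, 39 to 91 for liver day 21, 0 to 1 for intestine day 3, 0 to 1 for intestine day 21, 0 to 47 for the day difference in liver, 0 to 1 for the day difference in intestine, 1 to 6 for control liver over time, 11 to 68 for control intestine over time and 23 to 57 for the tissue difference at day 21. List counts ranged over 4 to 10 for liver day 3, 3 to 9 for intestine day 3 and 1 to 10 for intestine day 21. For lists whose direction turned, the adjusted p ranged over 1.69e-09 to 0.8 for the cell cycle list in liver day 3, 8.78e-06 to 0.97 for the germ cell markers list in liver day 3, 1.81e-05 to 0.809 for the oxidative phosphorylation list in liver day 21, 2.39e-07 to 0.499 for the hepatocyte markers list in liver day 21, 6.8e-05 to 0.994 for the enterocyte markers list in liver day 21, 4.41e-07 to 0.957 for the oxidative phosphorylation list in intestine day 3 and 7.89e-06 to 0.974 for the oxidative phosphorylation list in intestine day 21. Gene differences whose sign turned ranged as follows: in liver day 3, cyp1a -0.15 to 0.44, fabp10a -0.28 to 0.0624 and il1b -0.37 to 0.11. In liver day 21, cat -0.27 to 0.41, cyp1a -0.58 to 0.45, hmox1a -0.24 to 0.22, hsp70l -0.53 to 0.10 and sod1 -0.58 to 0.23. In intestine day 3, cyp1a -0.15 to 0.14, fabp10a -0.95 to 1.07, gclc -0.13 to 0.0285, hmox1a -0.44 to 0.15, il1b -0.42 to 0.11 and mt2 -0.46 to 0.25. In intestine day 21, cat -0.0144 to 0.37, cyp1a -0.25 to 0.19, fabp10a -0.45 to 0.25, hmox1a -0.51 to 0.60, hsp70l -0.0892 to 0.40, il1b -0.20 to 0.80 and sod1 -0.0892 to 0.24. The counts outside 1.5 times the reported one were these. In liver at day 3 there were 0 probes without control replicate 1, 2 or 5 or exposed replicate 2, 4 or 5, 2 without control replicate 3 and 3 without exposed replicate 1. In liver at day 21 there were 39 without control replicate 2. In intestine 1 probe was called at day 3 without control replicate 2 and 1 at day 21 without control replicate 3. For the day difference in liver there were 31 without exposed replicate 1 and 1 without exposed replicate 3 at day 3, and 47 without exposed replicate 4 at day 21. For the day difference in intestine there was 1 without control replicate 3 at day 21 and 1 without exposed replicate 5 at day 3. In control liver there were 2 without replicate 1 and 1 without replicate 5 at day 3. In control intestine there were 19, 14, 15 and 11 without replicates 1, 2, 3 and 5 at day 3, and 20, 15 and 16 without replicates 2, 3 and 5 at day 21. The tissue difference at day 21 had 23 without exposed intestine replicate 3. Lists numbered 10 in liver at day 3 without exposed replicate 4, 3 in intestine at day 3 without control replicate 1, and 1, 8, 7 and 10 in intestine at day 21 without control replicates 1, 2 and 5 and exposed replicate 3.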

Other observations

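The tests of slide, control arrays and hour for the clock genes, and those of the histocompatibility genes, were chosen after the result was seen. In liver at day 21, camera called further lists at its preset correlation, and these calls were lost with an estimated correlation. Ribosomal protein genes were higher in 79 of 80 (mean 0.44, adjusted p = 4.71e-17, adjusted p = 0.546 with an estimated correlation), with rplp1 at 0.95 and rps28 at 0.75, and their direction turned with quantile normalization. Acute phase and complement genes were higher in 47 of 58 (mean 0.57, adjusted p = 2.62e-05, adjusted p = 0.76 with an estimated correlation), with the complement gene c7b at 2.97 and cfhl2 at 2.57. That call ended without control replicate 4, the array low in hepatocyte markers (adjusted p 0.583), and the means within the first and second scan were 1.07 and 0.07. Oxidative phosphorylation genes were higher in 71 of 87 (mean 0.21, adjusted p = 0.00713, adjusted p = 0.889 with an estimated correlation) and leukocyte markers in 35 of 52 (mean 0.22, adjusted p = 0.0492, adjusted p = 0.855 with an estimated correlation). Without control replicate 4 the direction of the oxidative phosphorylation list turned (adjusted p 0.412), and without exposed replicate 1 or 5 its call ended (0.0773 and 0.809). The leukocyte call ended without any of 5 single arrays, control replicates 1 and 3 and exposed replicates 2, 3 and 4 (0.146 to 0.969), with means of 0.71 and -0.33 within the scans. Without control replicate 1 the leukocyte mean turned, to -0.007. Lower were interferon response genes in 41 of 53 (mean -0.36, adjusted p = 0.00335, adjusted p = 0.855 with an estimated correlation), such as the signalling gene mavs at -0.68, and p53 and apoptosis genes in 40 of 57 (mean -0.19, adjusted p = 0.0069, adjusted p = 0.546 with an estimated correlation), such as aifm2 at -1.18. The interferon call ended without control replicate 2 (0.447) or exposed replicate 5 (0.0506). Clock genes were lower in 33 of 46 (mean -0.16, adjusted p = 0.0267, adjusted p = 0.546 with an estimated correlation), with cry2 at -0.73, and their call ended without control replicate 4 (0.135) or exposed replicate 2 (0.0684). Muscle markers were lower in 29 of 41 (mean -0.56, adjusted p = 0.0144), enterocyte markers in 39 of 48 (mean -0.68, adjusted p = 0.028), both at adjusted p = 0.855 with an estimated correlation, and nervous and swim bladder markers in 23 of 31 (mean -0.61, adjusted p = 0.00335, adjusted p = 0.546 with an estimated correlation). Without control replicate 4 the enterocyte direction turned (0.994), and its call ended without control replicate 2 or exposed replicate 1 or 5 (0.332, 0.0773 and 0.512). The muscle call ended without control replicate 4 or exposed replicate 5 (0.412 and 0.23), and the nervous and swim bladder call without exposed replicate 5 (0.0589). Within the scans the means were -0.09 and -1.53 for enterocyte markers and 0.02 and -1.42 for muscle markers. Without the arrays high in germ cell or low in hepatocyte markers, the calls of the acute phase (0.31), oxidative phosphorylation (0.683), clock (0.3), enterocyte (0.972), muscle (0.494) and leukocyte lists (0.133) ended.

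In control intestine from day 3 to day 21, heat shock and chaperone genes were lower in 32 of 49 (mean -0.26, adjusted p = 0.000418, adjusted p = 0.388 with an estimated correlation), and 7 fell when adjusted over the list alone, 2 over all genes. Cholesterol synthesis genes were lower in 27 of 35 (mean -0.36, adjusted p = 1.23e-05, adjusted p = 0.388 with an estimated correlation), with ebp among the 2 that fell when adjusted over the list alone. Xenobiotic metabolism genes were lower in 65 of 89 (mean -0.25, adjusted p = 2.79e-06, adjusted p = 0.627 with an estimated correlation). Interferon response genes were higher in 47 of 53 (mean 0.42, adjusted p = 0.00211, adjusted p = 0.861 with an estimated correlation). Without 1 array the means of the cholesterol synthesis, xenobiotic and interferon lists were -0.23 (control replicate 4 at day 3), -0.17 (replicate 2 at day 21) and 0.22 (replicate 3 at day 3). In control liver over the same time, cell cycle genes were lower in 105 of 113 (mean -1.10, adjusted p = 8.64e-18) and germ cell markers in 54 of 59 (mean -2.05, adjusted p = 4.3e-15), both at adjusted p = 0.846 with an estimated correlation. Without control replicate 5 at day 3, an array high in germ cell markers, these means were -0.61 and -1.33.

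For the 7 clock genes past the threshold in control intestine, 21 of 21 changes between the days within a slide of liver controls, which had no part in choosing the genes, had the same direction, which argues against a slide as the cause. The change was not limited to the control arrays, since in the exposed arrays of both tissues 8 of 14 changes of these genes passed adjusted p 0.05 in the same direction. The hour of sampling could not be told apart from the day, because the labels give no hour and each day holds its own arrays, and 20 of 46 clock genes measured in intestine had an unadjusted p under 0.05. A change over the feeding time remains open as well.

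A hypothesis on the histocompatibility genes is that each intestine array may hold 1 fish, where the series text gives 4 per sample. A single fish carries at most 2 of the 3 types, and 19 of 19 intestine arrays did at the threshold of -4, on which that count rests. Pools of 4 would do so in 29.7% by the shares on these arrays. Those shares took each array as 1 fish with 2 copies, so that the figure assumes the hypothesis and cannot decide on it. The level of mhc1uba was 7.59 ± 0.18 (SD, n = 7) where it stood alone and 6.48 ± 0.42 (SD, n = 6) beside another type, a difference of 1.1 (exact permutation test, two-sided, p = 0.000583). A probe that fails on some arrays is argued against, because psmb8f, psmb9b and mhc1uaa were all present or all absent on 19 of 19 intestine arrays. The type counts and the mhc1uba levels met what had been written down for 1 fish per array. A type would be dimmer beside another in a mixed pool too, so that the levels cannot decide between 1 fish and 4. Pools of related fish remain open.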
